A study of Mus musculus with 14 samples.

How the data were processed

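Gene expression was measured in whole lungs of wild type mice (4 samples), CD151KO mice (5) and CD9KO mice (5). Per the labels, lungs were homogenised in a lysis reagent, total RNA was purified on columns, and biotin-labelled RNA was made from it for 1-colour Affymetrix arrays. Groups and replicate numbers were taken from the sample titles. The labels do not say that the samples of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

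The deposited values are normalized intensities, 1 per probe set and array, on a linear scale, and per the labels each column is normalized. Affymetrix Expression Console and MAS5 are named per the submitters' processing notes, with no version or role. Of the 45101 probe sets, 2322 (5.15%) had exactly equal values on at least a pair of arrays, which is unusual for MAS5, since it treats each array on its own. Which method summarised and normalized the values is not given in the sources used here, and low signals depend on it. Values ran from 4.78 to 29667, the array medians from 84.1 to 86.2, and the lowest correlation of log2 values between any pair of arrays was 0.9906. For arrays, the number of samples limits the precision, and signals near the background limit the fold changes of weakly expressed genes.

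Probe sets were named from the platform annotation, in which 34958 had 1 gene symbol, 932 had several and 9211 had none. Of those with 1 symbol, 34754 were matched by Entrez gene ID to a gene table of assembly GRCm38.p6, and 0 symbols needed an update. Probe sets with several symbols or none, and 64 control probe sets, were not tested. A gene was represented by its probe set with the highest mean over the 14 arrays, which gave 18194 genes. Genes whose mean log2 level lay below the 40th percentile of all probe sets other than controls (log2 6.12, a signal of 53.4) were left out, 5208 in number, and 12986 were tested.

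Values were transformed as log2(signal + 16), so fold changes are on that scale and understate the change of genes with low signal. A linear model with the 3 groups was fitted to all 14 arrays with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a mean-variance trend). It had 11 residual degrees of freedom, and the median residual SD of a gene was 0.0882 on the log2 scale. The 3 contrasts were tested, each two-sided, with Benjamini-Hochberg adjustment over the 12986 genes, and a gene passed at an adjusted p under 0.05. Adjusted p-values of single genes are limma's throughout. No further normalization between arrays was applied.

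Gene lists for lung cell types, the matrix, tetraspanin partners, stress responses and possible admixed tissues were tested with camera (limma, two-sided) at a preset correlation of 0.01 and adjusted over the lists of a comparison. Cd151 and Cd9 were left out of every list. Of 44 lists, 43 had at least 4 measured genes and were tested, with 706 of 857 entries measured. Each list was also tested with a correlation estimated from the residuals, and its members were adjusted over the list alone. Genes near a knocked-out gene were compared with all others by Fisher's exact test over a window of 20 Mb. Array measures were compared by exact two-sided permutation tests. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

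The groups, tests, gene lists, alternatives and the rule for the genes named were fixed before the data were examined. Named genes were Cd151 and Cd9, the 10 largest rises and the 10 largest falls among genes that passed and whose groups did not overlap, up to 4 members of each described list by smallest unadjusted p, and up to 5 genes per direction for genes changed in both knockouts. Genes outside the rule are said to have been chosen after their values were seen.

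The procedure was tested on simulated data of these 12986 genes, in 5 sets with 200 genes changed. For CD151KO against wild type, 30.7% of genes changed by 0.2 on the log2 scale were recovered, 84.2% at 0.4 and 98.2% at 0.8, and 3.67% of calls were false. For CD151KO against CD9KO the shares were 36.1%, 85.4% and 98.2%, with 6.40% false. A gene list shifted by 0.1 was called in 5 of 5 sets. The simulated noise was drawn independently for each gene. These shares therefore do not cover arrays on which genes vary together, and the 5 of 5 does not test the preset correlation.

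The alternatives were pseudocounts of 1 and 64, quantile normalization, centring of arrays on their median, no filter and a filter at the 60th percentile, the mean of all probe sets of a gene, every probe set, only the compared groups in the fit, no trend, array weights, the replicate number as a block, no moderation, a fold of at least 1.5, other windows, and leaving out each array in turn. Leaving out the arrays that stood apart on the first principal component, and the first component of the residuals as a covariate, were added after seeing the data.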

Results

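Total RNA from whole lungs of C57BL/6 mice aged 20 weeks was measured on Affymetrix expression arrays, with 1 array per sample. By their labels the 14 samples fell into 3 groups. Wild type mice gave 4 samples, numbered 1, 3, 4 and 5, mice lacking CD151 (CD151KO) gave 5, and mice lacking CD9 (CD9KO) gave 5. CD151 and CD9 are tetraspanins, small membrane proteins that organise other membrane proteins such as integrins, and CD151 binds the laminin-binding integrins of epithelial cells. The study's title concerns CD151, the epithelium and fibrosis of the lung, so the comparisons asked which transcripts differed in lungs without CD151, which differed in lungs without CD9, and whether the knockouts differed from each other. Each array gave 45101 probe sets, groups of probes that measure 1 transcript, in linear signal units from 4.78 to 29667. The array medians lay between 84.1 and 86.2. After a filter on low signal 12986 genes were tested. The number of arrays limits the precision of every value.

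Each knocked-out gene was low in its own knockout. Cd151 had a signal of 5330 ± 372 in wild type (SD, n = 4) and 1058 ± 17.7 in CD151KO (n = 5), a fall of 4.97-fold on the log2(signal + 16) scale (log2 -2.31, SE 0.04, limma adjusted p = 8.8e-15), and 4987 ± 149 in CD9KO (n = 5). The range of Cd151 in CD151KO was 1027 to 1072, and in wild type 4991 to 5833. Of the 6 probe sets for Cd151, 4 had a wild type signal 4.86 to 5.55 times that in CD151KO. The remaining pair measured 55.5 ± 7.05 and 136 ± 5.21 in wild type against 48.1 ± 5.84 and 129 ± 6.52 in CD151KO. Which part of the gene was deleted is not given in the sources used here, so a probe set that did not move checks nothing. With the mean of all 6 the log2 change in CD151KO was -1.60. Cd9, with 1 probe set, had a signal of 8096 ± 69.4 in wild type, 8232 ± 265 in CD151KO and 667 ± 52.3 in CD9KO, a fall of 11.9-fold in CD9KO (log2 -3.57, SE 0.05, adjusted p = 9.2e-17). Cd9 in CD151KO (log2 0.02, adjusted p = 0.906) and Cd151 in CD9KO (log2 -0.09, adjusted p = 0.167) did not pass the test.

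**Figure D1:**
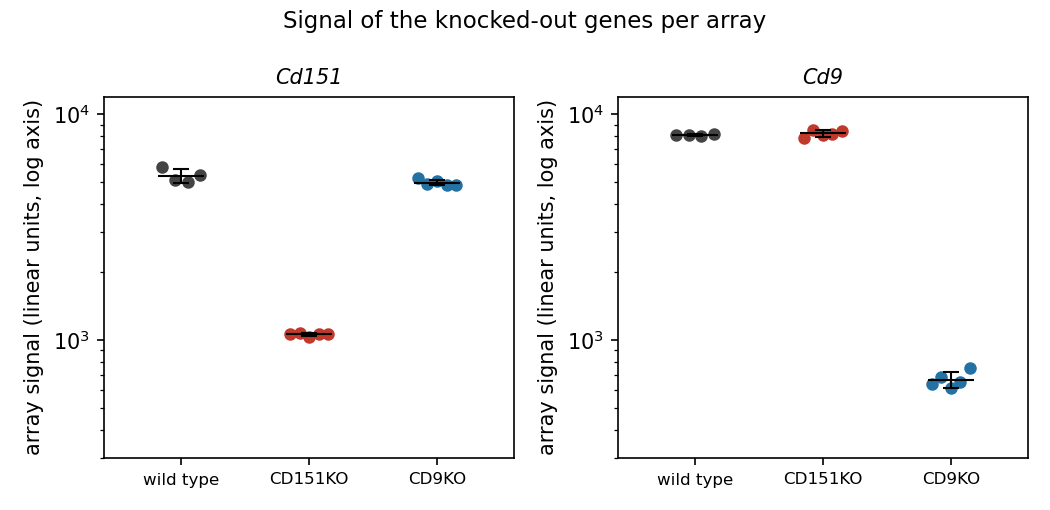
Signal of Cd151 (left) and Cd9 (right) per array in linear units on a log axis, with 1 point per array and bars at the group mean ± SD (n = 4 in wild type and 5 in each knockout). The CD151KO arrays lie between 1027 and 1072 for Cd151, and the CD9KO arrays between 614 and 749 for Cd9, all below the arrays of the other groups.

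Array number 1 of wild type and array number 1 of CD151KO stood apart from the other 12 on the first principal component of the genes tested, which held 37.5% of the variance. They scored -18.5 and -17.2, and the others between -8.01 and 13.4. CD9KO scored 9.52 ± 2.47 (SD, n = 5) on it and wild type -5.29 ± 9.26 (n = 4), which an exact two-sided permutation test separated (p = 0.0079, adjusted p = 0.040 over 15 tests of array measures). CD151KO scored -5.29 ± 7.93 (n = 5) and was separated from CD9KO with the same exact p and adjusted p. The signal of these 2 arrays lay outside that of the other 12 in 7 of 43 gene lists. Their mean log2 signal was higher for B and plasma cell markers (8.51 and 8.83, others 7.63 to 8.17), immediate early genes (10.3 and 10.2, others 9.70 to 9.96), mesenchymal transition regulators (9.69 and 9.75, others 9.46 to 9.66) and cytosolic ribosomal proteins (13.02 and 13.01, others 12.88 to 12.97). It was lower for heat shock and chaperone genes (10.8 and 11.3, others 11.5 to 12.01), the unfolded protein response (10.1 and 10.2, others 10.3 to 10.5) and p53 targets (9.29 and 9.31, others 9.38 to 9.57). Eif2s3y, a gene of the Y chromosome, had a signal of 582 to 744 on the 14 arrays, and Xist, transcribed from an inactive X, 45.6 to 83.6. The bacterial control BioB, a labelled RNA added at hybridization, gave 332 ± 16.4 in wild type (n = 4) and 387 ± 24.5 in CD151KO (n = 5) (exact permutation p = 0.0079, adjusted p = 0.040), and 412 ± 39.97 in CD9KO (n = 5) (exact permutation p = 0.024, adjusted p = 0.071). Every wild type array (314 to 354) lay below every CD151KO array (363 to 424) and every CD9KO array (361 to 444). A technical difference between the wild type and knockout arrays is therefore not excluded, and what it adds to the comparisons against wild type was not tested. The ratio of 3' to 5' probe signal for Gapdh, a sign of RNA quality, was 0.851 ± 0.012 in wild type (n = 4), 0.869 ± 0.013 in CD151KO (n = 5) and 0.856 ± 0.022 in CD9KO (n = 5), with the lowest exact permutation p of its 3 comparisons at 0.071 (adjusted p = 0.179). The lowest for the same ratio of Actb was 0.206 (adjusted p = 0.442). The control for 18S ribosomal RNA gave 1474 ± 352 in wild type (n = 4), 1650 ± 226 in CD151KO (n = 5) and 1312 ± 106 in CD9KO (n = 5), with an exact permutation p of 0.024 between the knockouts (adjusted p = 0.071).

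**Figure D2:**
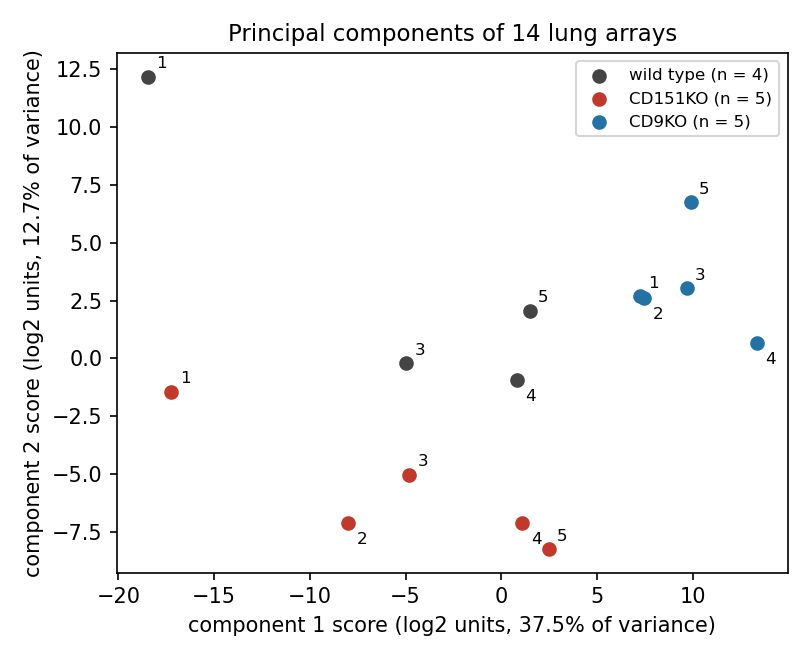
Scores of the 14 arrays on the first and second principal components in log2 units, with 1 point per array, coloured by group and numbered by replicate. Wild type and CD151KO number 1 lie at -18.5 and -17.2 on component 1, and all CD9KO arrays lie at or above 7.23.

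In lungs without CD151, genes of the circadian clock and of the extracellular matrix were among the largest changes against wild type. Arntl, the activator at the core of the circadian clock, rose 2.15-fold, from 71.2 ± 6.83 (SD, n = 4) to 178 ± 53.2 (n = 5) (log2 1.11, SE 0.16, adjusted p = 0.0048). Clock-controlled transcription factors went the other way. Dbp fell 1.81-fold (log2 -0.86, SE 0.16, adjusted p = 0.024), Hlf 1.56-fold (log2 -0.64, SE 0.09, adjusted p = 0.0048) and Tef 1.37-fold (log2 -0.45, SE 0.07, adjusted p = 0.0062). The clock repressors Per3 and Ciart fell 1.52-fold and 1.53-fold (adjusted p = 0.0048 and 0.030). The hour at which lungs were taken is not given in the sources used here. In all, 101 of 12986 genes passed, of which 59 rose and 42 fell, with 1445 at an unadjusted p under 0.05. Of the 101, 14 changed at least 1.5-fold.

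The other large rises in CD151KO included genes of the extracellular matrix. Mfap5, which codes for a microfibril protein, rose from 739 ± 61.1 to 1136 ± 31.5 (1.53-fold, adjusted p = 2.6e-04), Col3a1 (type III collagen) from 2434 ± 314 to 3572 ± 285 (1.47-fold, adjusted p = 0.030), Eln (elastin) from 188 ± 25.0 to 287 ± 46.1 (1.48-fold, adjusted p = 0.030) and Spon2 from 76.0 ± 8.96 to 131 ± 31.1 (1.58-fold, adjusted p = 0.020). Rbp7, a retinol-binding protein gene, rose 2.17-fold with a wide spread in the knockout (49.6 ± 1.76 to 137 ± 64.9, adjusted p = 0.042). Stk32c (1.56-fold), Nrcam (1.52-fold), Parm1 (1.47-fold) and Leo1 (1.46-fold) made up the rest of the 10. Among the falls were the tetraspanin gene Tspan4, from 1995 ± 91.7 to 1159 ± 154 (1.72-fold, adjusted p = 2.6e-04), Gm33248 (1.59-fold), Ccbe1 (1.53-fold) and Mthfd1l, a mitochondrial folate enzyme (1.47-fold). Of the 19 largest changes other than Cd151, 11 passed in each alternative fit that tested them, which was 28 fits, or 27 for Arntl, Leo1, Stk32c and Gm33248, which a filter at the 60th percentile left out. The limit of 1.5-fold and the test of every probe set were applied to counts of calls and not to single genes. The 11 were Arntl, Mfap5, Parm1, Leo1, Stk32c, Tspan4, Gm33248, Hlf, Per3, Ccbe1 and Mthfd1l.

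Of the 43 gene lists tested, 16 passed in CD151KO against wild type, 12 higher and 4 lower, and 0 passed with an estimated correlation (camera, 8 at an unadjusted p under 0.05). The circadian clock list stood lower (median log2 -0.36, camera adjusted p = 7.1e-09, adjusted p = 0.181 with an estimated correlation): of 18 genes 2 rose, 7 fell and 9 did not pass, and adjusted over the list alone 3 rose and 11 fell. Interstitial and fibrillar matrix genes stood higher (median 0.14, adjusted p = 5.4e-07, adjusted p = 0.261 with an estimated correlation). Of 27, 3 rose (Col3a1, Eln and Col5a2, the last by 1.30-fold) and 24 did not pass, with 10 risen adjusted over the list alone, and Lox measured 512 ± 27.0 and 747 ± 155 (adjusted p = 0.078). Without wild type number 4 the median was 0.091. Basement membrane genes stood higher (median 0.08, adjusted p = 2.0e-04, adjusted p = 0.181 with an estimated correlation) with 0 of 21 passing by limma, 5 at an unadjusted p under 0.05 and 2 adjusted over the list alone. Col4a1 had a log2 difference of 0.19 and Col4a2 of 0.14 (adjusted p = 0.078 and 0.072), and the list median was 0.049 with the mean of all probe sets of a gene. Smooth muscle and myofibroblast contractile genes stood higher (median 0.12, adjusted p = 1.7e-05, adjusted p = 0.261 with an estimated correlation): 1 of 15 rose, the smooth muscle actin Actg2 (1.31-fold, adjusted p = 0.025), and 5 rose adjusted over the list alone. Matrix proteases and inhibitors stood higher (median 0.14, adjusted p = 0.027, adjusted p = 0.181 with an estimated correlation), with 1 of 19 risen, the sheddase gene Adam17 (1.12-fold, adjusted p = 0.030), and 5 risen and 1 fallen adjusted over the list alone. That call ended without wild type number 5 (adjusted p = 0.094). The median was 0.062 without wild type number 1, 0.069 without CD151KO number 4 and 0.091 with no filter or with the mean of all probe sets. The laminin-binding integrin and hemidesmosome list, which holds the partners of CD151, stood higher (median 0.09, adjusted p = 0.020, adjusted p = 0.216 with an estimated correlation) with 0 of 8 passing by limma, 4 at an unadjusted p under 0.05 and 1 adjusted over the list alone. Itga3, Itga6, Itga7 and Itgb4 had log2 differences of 0.11, 0.23, 0.28 and 0.18, and the call ended without wild type number 3 (adjusted p = 0.083) or CD151KO number 5 (adjusted p = 0.051). The list median was 0.048 with no filter.

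Some epithelial lists stood higher or lower in CD151KO, and others did not pass. Club and secretory cell markers, keratins and damaged epithelium, and epithelial junctions did not pass, nor did fibroblast markers or TGF-beta genes. Over the alternatives the smallest camera adjusted p of these lists was 0.17, 0.20, 0.22, 0.39 and 0.38. Alveolar type 2 markers stood higher (median 0.04, adjusted p = 0.0048, adjusted p = 0.415 with an estimated correlation): 2 of 20 rose, Cxcl15 (1.21-fold, adjusted p = 0.016) and S100g (1.25-fold, adjusted p = 0.045), and 3 rose adjusted over the list alone. The median was 0.060 without wild type number 1 and 0.021 without number 5. Alveolar type 1 markers stood lower (median -0.05, adjusted p = 0.014, adjusted p = 0.723 with an estimated correlation) with 0 of 16 passing by limma, 5 at an unadjusted p under 0.05 and 0 adjusted over the list alone. Pdpn and Hopx had log2 differences of -0.19 and -0.05. This call ended without wild type number 3 (adjusted p = 0.134), CD151KO number 3 (0.090) or CD151KO number 5 (0.102), and the median was -0.084 without CD151KO number 2. Ciliated cell markers stood higher (median 0.07, adjusted p = 0.030, adjusted p = 0.785 with an estimated correlation) with 0 of 18 passing by limma, 2 at an unadjusted p under 0.05 and 0 adjusted over the list alone, and Foxj1 had a log2 difference of 0.23. It ended without wild type number 5 (adjusted p = 0.248) or CD151KO number 1 (0.081), 4 (0.054) or 5 (0.181), and with the first component of the residuals as a covariate (0.0503), an alternative chosen after seeing the data. The median fell to 0.036 without wild type number 5 and to 0.022 without CD151KO number 5. Mesenchymal transition regulators stood lower (median -0.07, adjusted p = 0.029, adjusted p = 0.450 with an estimated correlation) with 0 of 10 passing by limma, 2 at an unadjusted p under 0.05 and 0 adjusted over the list alone. Vim and Zeb1 had log2 differences of -0.11 and -0.18. It ended with no level filter (adjusted p = 0.270), with the mean of all probe sets of a gene (0.051), and without wild type number 1 (0.055) or CD151KO number 4 (0.094) or 5 (0.102). On this list both number 1 arrays lay above the other 12.

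Lipid genes and markers of other cells also differed between CD151KO and wild type. Lipid and cholesterol synthesis genes stood higher (median 0.11, adjusted p = 1.0e-07, adjusted p = 0.232 with an estimated correlation): Fasn, the fatty acid synthase gene, rose 1.38-fold from 1652 ± 131 (n = 4) to 2288 ± 165 (n = 5) (adjusted p = 0.0048), the other 21 did not pass, and 7 rose adjusted over the list alone. The median was 0.17 without wild type number 1 and 0.19 without number 3. Scd1, which this list shares with the adipose list, measured 9938 ± 1303 and 13911 ± 1827 (adjusted p = 0.057). Adipose genes stood higher (median 0.26, adjusted p = 5.5e-04, adjusted p = 0.450 with an estimated correlation) with 0 of 10 passing by limma, 4 at an unadjusted p under 0.05 and 3 adjusted over the list alone, and Adipoq had a log2 difference of 0.60. Neutrophil markers stood higher (median 0.33, adjusted p = 6.1e-04, adjusted p = 0.181 with an estimated correlation) with 0 of 10 passing by limma, 5 at an unadjusted p under 0.05 and 1 adjusted over the list alone. S100a8 measured 3088 ± 1791 in CD151KO and 1512 ± 733 in wild type. Cardiac muscle genes stood higher (median 0.13, adjusted p = 0.030, adjusted p = 0.798 with an estimated correlation) with 0 of 18 passing by limma, 3 at an unadjusted p under 0.05 and 0 adjusted over the list alone. That call ended without wild type number 1 (adjusted p = 0.323) or 5 (0.116), without CD151KO number 3 (0.300) or 5 (0.356), without both number 1 arrays (0.111), and with the residual component as a covariate (0.0512). The median fell to 0.070 without CD151KO number 3, 0.052 without number 5 and 0.084 with the mean of all probe sets, and was 0.19 without CD151KO number 2. The unfolded protein response stood higher (median 0.10, adjusted p = 0.014, adjusted p = 0.768 with an estimated correlation) with 0 of 20 passing by limma, 7 at an unadjusted p under 0.05, and 2 risen and 1 fallen adjusted over the list alone. Pdia4 and Atf4 had log2 differences of 0.19 and -0.15. Both number 1 arrays lay below the other 12 on this list, and the call ended without wild type number 1 (0.497, median 0.059), CD151KO number 5 (0.091) or both number 1 arrays (0.070). Immediate early genes stood lower (median -0.09, adjusted p = 0.0089, adjusted p = 0.450 with an estimated correlation) with 0 of 22 passing by limma, 2 at an unadjusted p under 0.05 and 1 fallen adjusted over the list alone. Klf6 had a log2 difference of -0.19. On this list both number 1 arrays lay above the other 12, and the call ended without wild type number 1 (adjusted p = 0.142, median -0.020). The median was -0.17 without wild type number 5 and -0.052 without CD151KO number 3.

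The size of the CD151KO result depended on single arrays. Against 101 genes with all arrays, 60, 24 and 41 passed without wild type number 3, 4 and 5, 55, 54 and 31 without CD151KO number 3, 4 and 5, and 45 without the number 1 arrays of wild type and CD151KO, an alternative chosen after seeing the data. Of the 39 passing genes named for this comparison, leaving out wild type 1, 3, 4 or 5 ended 15, 15, 24 or 17 calls. Leaving out CD151KO 1 to 5 ended 10, 13, 14, 14 and 21, and CD9KO 1 to 5, which enter through the shared spread, ended 2, 3, 7, 3 and 5, at adjusted p from 0.050 to 0.158.

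**Figure D3:**
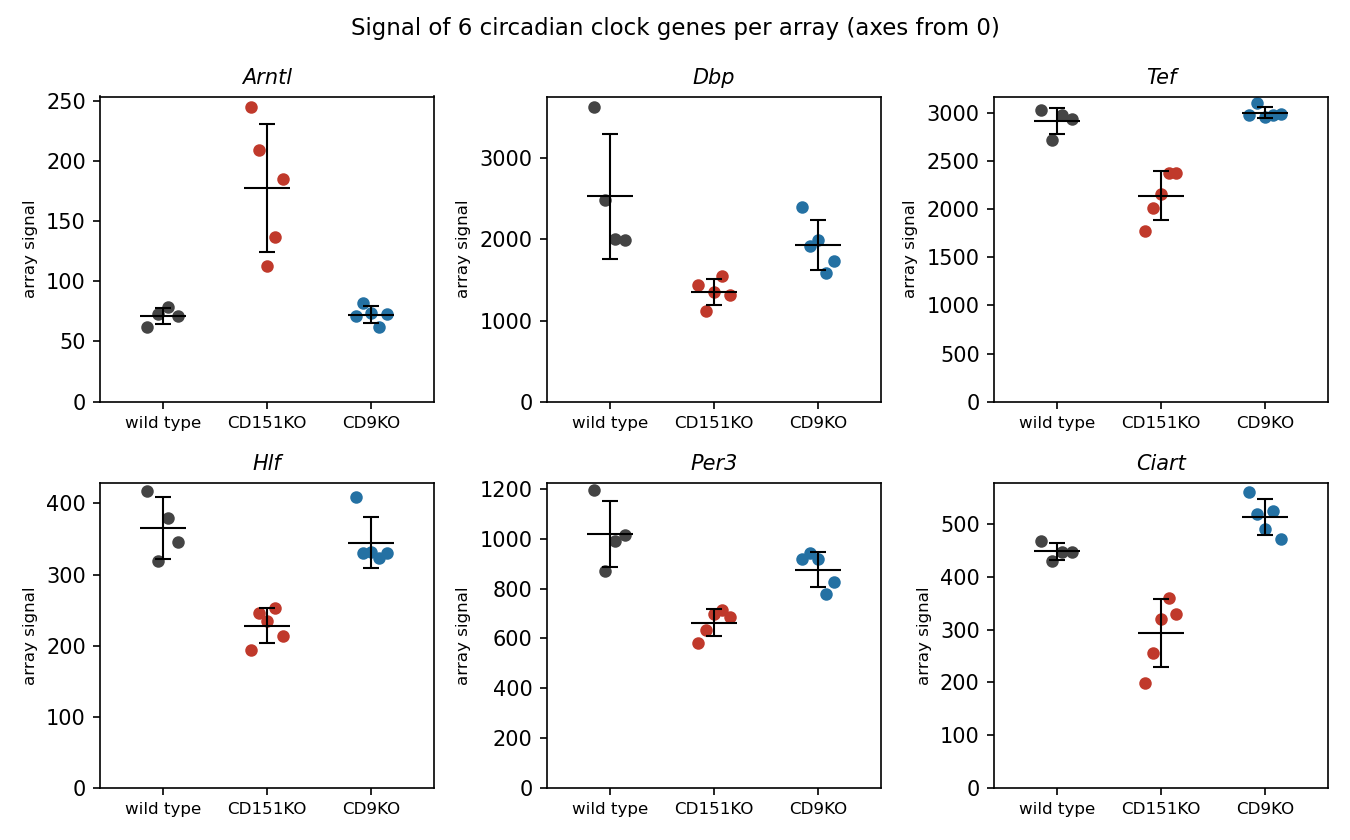
Array signal in linear units, on axes from 0, of the clock genes Arntl, Dbp, Tef, Hlf, Per3 and Ciart, with 1 point per array and bars at the group mean ± SD (n = 4 in wild type and 5 in each knockout). Arntl lies higher on every CD151KO array than on any wild type or CD9KO array (178 ± 53.2 against 71.2 ± 6.83 and 72.4 ± 7.09), and the other 5 genes lie lower in CD151KO than in wild type on every array.

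In lungs without CD9 most of the changes against wild type were small. Myh6, the alpha heavy chain of cardiac myosin, rose 1.65-fold, from 1111 ± 177 (SD, n = 4) to 1844 ± 284 (n = 5) (log2 0.72, SE 0.17, adjusted p = 0.028). Over the alternative fits its log2 change ran from 0.38 to 0.81, and its call was lost in 6 of 28. Cd163, a scavenger receptor gene of macrophages, rose 1.66-fold (log2 0.73, SE 0.19, adjusted p = 0.040), Plat, the tissue plasminogen activator gene, 1.68-fold (log2 0.75, SE 0.20, adjusted p = 0.044) and Tinagl1, a matrix protein gene, 1.73-fold (log2 0.79, SE 0.18, adjusted p = 0.028). Bdnf, a neurotrophin gene, fell 1.46-fold, from 456 ± 11.8 to 310 ± 39.9 (adjusted p = 0.023), and Elf5, which codes for an epithelial transcription factor, fell 1.51-fold (adjusted p = 0.028). In all, 715 of 12986 genes passed, of which 374 rose and 341 fell, with 3304 at an unadjusted p under 0.05. Only 26 of the 715 changed at least 1.5-fold, and the median change was 1.19-fold.

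The largest rise in CD9KO was that of Pcdh20, a protocadherin gene, from 52.2 ± 9.46 to 138 ± 55.3 (2.15-fold, adjusted p = 0.017). Klhl29 rose 1.97-fold, Myrip 1.95-fold, the metalloprotease gene Adamts15 1.85-fold, Mfsd2a, a lipid transporter gene, 1.67-fold and A4galt 1.65-fold. The largest falls after Cd9 were Bex2 (1.77-fold, from 916 ± 199 to 507 ± 68.6), Gulp1, whose product acts in the engulfment of dying cells (1.61-fold), and Mthfd1, the cytosolic folate enzyme (1.60-fold). Ndnf (1.53-fold), Lrrc17 (1.47-fold), Lzts1 (1.47-fold) and Kdm5a (1.46-fold) followed. Of these 19 genes Bex2, Gulp1 and Mfsd2a passed in each alternative fit that tested them (28, 28 and 27 fits). Plat had another probe set of opposite sign (log2 -0.05). Of the other probe sets of Kdm5a, log2 values of 0.05 and 0.13 had the opposite sign and -0.09 the same. Kdm5a did not pass with the mean of all its probe sets (log2 -0.06, adjusted p = 0.301, the highest over its alternatives).

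Of the 43 gene lists, 11 passed in CD9KO against wild type, 6 higher and 5 lower, and 0 passed with an estimated correlation (camera, 1 at an unadjusted p under 0.05). Cardiac muscle genes stood higher (median log2 0.38, adjusted p = 1.4e-05, adjusted p = 0.771 with an estimated correlation): of 18, 2 rose (Myh6 and Hspb7, the latter by 1.45-fold from 162 ± 16.8 to 240 ± 8.38), 16 did not pass, and 10 rose adjusted over the list alone. Smooth muscle and myofibroblast contractile genes stood higher (median 0.14, adjusted p = 6.5e-04, adjusted p = 0.771 with an estimated correlation). Here 5 of 15 rose, among them Actg2 (1.42-fold), Cnn1 (1.38-fold), Myh11 (1.23-fold) and Lmod1 (1.14-fold), 10 did not pass, and 7 rose adjusted over the list alone. The median was 0.088 without CD9KO number 1 and 0.057 with the mean of all probe sets of a gene. The unfolded protein response stood higher (median 0.25, adjusted p = 1.4e-05, adjusted p = 0.771 with an estimated correlation). The endoplasmic reticulum chaperone genes Hyou1 (1.19-fold), Pdia4 (1.19-fold) and Calr (1.21-fold) were among 6 of 20 that rose, the regulator Atf4 fell (1.12-fold), 13 did not pass, and adjusted over the list alone 15 rose and 2 fell. Both number 1 arrays lay below the other 12 on this list, and its median was 0.14 with the mean of all probe sets. Adipose genes stood higher (median 0.23, adjusted p = 6.5e-04, adjusted p = 0.771 with an estimated correlation): 3 of 10 rose, Car3 (1.56-fold), Plin4 (1.35-fold) and Pnpla2 (1.18-fold), 7 did not pass, and 5 rose adjusted over the list alone. The laminin-binding integrin and hemidesmosome list stood higher (median 0.14, adjusted p = 0.018, adjusted p = 0.771 with an estimated correlation), with 2 of 8 risen, Itga6 (1.28-fold) and Dst (1.19-fold, with another probe set of opposite sign), and 3 risen adjusted over the list alone. Its median was 0.064 with the mean of all probe sets. The glucocorticoid response stood higher (median 0.25, adjusted p = 0.018, adjusted p = 0.831 with an estimated correlation), with 1 of 14 risen, Sgk1 (1.24-fold, adjusted p = 0.045), and 3 risen adjusted over the list alone. Fkbp5, a standard target of the glucocorticoid receptor, measured 633 ± 271 in wild type and 1503 ± 341 in CD9KO (adjusted p = 0.083), and the list's call ended without wild type number 1 (adjusted p = 0.082) or 5 (0.076).

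Lists that stood lower in CD9KO than in wild type held genes of ciliated cells, ribosomes, mitochondria and B cells. Ciliated cell markers (median -0.12, adjusted p = 0.0086, adjusted p = 0.831 with an estimated correlation) had 1 of 18 fallen, Tmem212 (1.26-fold, adjusted p = 0.037), and 5 fallen adjusted over the list alone, and the call ended without CD9KO number 5 (adjusted p = 0.052, median -0.077). Cytosolic ribosomal proteins (median -0.06, adjusted p = 7.0e-04, adjusted p = 0.831 with an estimated correlation) had 1 of 13 fallen, Rpl11 (1.08-fold), which was also the only one adjusted over the list alone. On this list both number 1 arrays lay above the other 12, and the median was -0.038 without wild type number 1 or without both, and -0.035 with quantile normalization. Oxidative phosphorylation genes (median -0.04, adjusted p = 0.018, adjusted p = 0.831 with an estimated correlation) had 0 of 24 passing by limma, 7 at an unadjusted p under 0.05 and 2 fallen adjusted over the list alone. That call ended with quantile normalization (adjusted p = 0.052), with the mean of all probe sets of a gene (0.208), without wild type number 1 (0.090), without CD9KO number 5 (0.051) and without both number 1 arrays (0.099). The median was -0.030 with quantile normalization, -0.029 with the mean of all probe sets and -0.021 without wild type number 1 or without both. Immediate early genes (median -0.13, adjusted p = 0.043, adjusted p = 0.831 with an estimated correlation) had 0 of 22 passing by limma, 8 at an unadjusted p under 0.05, and 1 risen and 3 fallen adjusted over the list alone, and Atf3 had a log2 difference of -0.58. Egr3 had a log2 difference of 0.19 (adjusted p = 0.056), but of -0.62 with a pseudocount of 64, -0.34 with the mean of its probe sets and -0.87 on its other probe set, so its direction is not settled. The call ended without wild type number 1 (0.147) or 4 (0.053) or CD9KO number 3 (0.086) or 4 (0.066). It also ended without both number 1 arrays (0.078), and the median was -0.065 without wild type number 1 or without both. B and plasma cell markers (median -0.20, adjusted p = 0.0495, adjusted p = 0.855 with an estimated correlation) had 0 of 17 passing by limma, 1 at an unadjusted p under 0.05 and 0 adjusted over the list alone. Both number 1 arrays lay above the other 12 on this list and on the immediate early genes. The call ended without wild type number 1 (0.360) or 4 (0.098), CD151KO number 5 (0.054), CD9KO number 2 (0.111), 3 (0.086) or 4 (0.064), both number 1 arrays (0.148), and with the mean of all probe sets of a gene (0.174). It also ended with the replicate number as a block (0.078). The median was -0.092 without wild type number 1 or without both number 1 arrays, and -0.33 without wild type number 5.

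Leaving out wild type number 1 or 3 brought the 715 genes to 267 or 158, and leaving out CD9KO number 3, 4 or 5 to 335, 208 or 186. Without both number 1 arrays, chosen after seeing the data, 405 passed. Of the gene lists, 7 passed without wild type number 1, against 11 with all arrays. Of the 64 passing genes named for this comparison, leaving out wild type 1, 3, 4 or 5 ended 40, 42, 18 or 11 calls. Leaving out CD9KO 1 to 5 ended 14, 15, 30, 38 and 35, and CD151KO 2 to 5 ended 5, 11, 12 and 3, at adjusted p from 0.050 to 0.133.

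**Figure D4:**
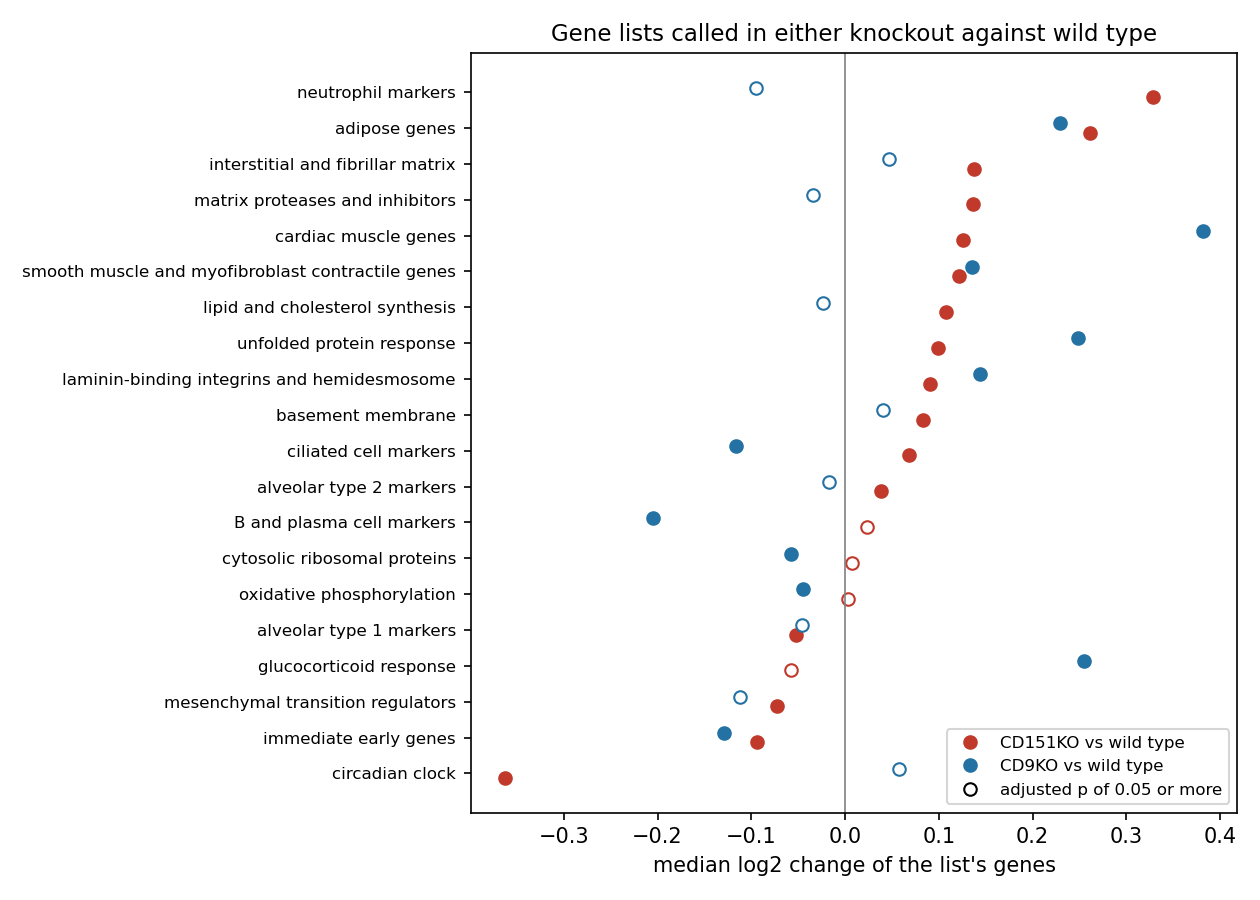
Median log2 change of the genes of each list that passed in either knockout against wild type (horizontal axis, log2 units), with 1 point per list and comparison, filled where camera's adjusted p was under 0.05 with the preset correlation and open where it was not. The circadian clock list lies at -0.36 in CD151KO, and the cardiac muscle list at 0.38 in CD9KO and 0.13 in CD151KO.

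Between the knockouts, S100a9 and S100a8, which code for calcium-binding proteins of neutrophils, were 3.42-fold and 3.05-fold higher in CD151KO than in CD9KO, with a wide spread in CD151KO (S100a9 2564 ± 1550 against 639 ± 102, SD, n = 5 each, log2 1.78, SE 0.36, adjusted p = 0.0081). Itgb6, the beta subunit of an integrin that activates TGF-beta, was 2.03-fold higher (240.0 ± 44.8 against 109 ± 8.83, log2 1.02, SE 0.14, adjusted p = 0.0011). Mfap5 was 1.92-fold higher (log2 0.94, SE 0.06, adjusted p = 3.3e-07). Of the clock genes, Arntl was 2.13-fold higher (log2 1.09, SE 0.15, adjusted p = 0.0011), and the repressors Ciart and Per2 were 1.74-fold and 1.71-fold lower (adjusted p = 0.0015 and 0.029). Cry1, another repressor, was lower in CD151KO (235.5 ± 60.8 against 476 ± 39.6, adjusted p = 0.0054). In all, 1313 of 12986 genes passed, 778 higher and 535 lower in CD151KO, with 3588 at an unadjusted p under 0.05. Of the 1313, 64 differed at least 1.5-fold.

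Cd9 and Cd151 led both directions (log2 3.60, SE 0.04, and -2.22, SE 0.04). The remaining large differences upward in CD151KO were those of Spink5, a protease inhibitor gene (2.47-fold), the cytokine gene Il1b (2.21-fold, 345 ± 203 against 130 ± 18.5), the immunoglobulin gene Iglv1 (2.18-fold) and Bex2 (1.96-fold). Downward they were those of Pcdh20 (2.28-fold), Cntn1 (1.93-fold), Fst, the follistatin gene (1.82-fold), Sema7a (1.69-fold), Resp18 (1.66-fold) and Tinagl1 (1.66-fold). Of the 18 largest differences other than the targets, 13 passed in each alternative fit that tested them (26 to 28 fits), and Iglv1, Il1b, Per2, Sema7a and Tinagl1 did not.

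Of the 43 gene lists, 15 passed between the knockouts, 10 higher and 5 lower in CD151KO, and 0 passed with an estimated correlation (camera, 3 at an unadjusted p under 0.05). The circadian clock list stood lower (median log2 -0.40, adjusted p = 1.5e-05, adjusted p = 0.614 with an estimated correlation): 1 of 18 was higher, 12 were lower, among them Usp2 (1.52-fold) and Tef (1.41-fold), and 5 did not pass, with 2 and 12 adjusted over the list alone. Ciliated cell markers stood higher (median 0.18, adjusted p = 1.5e-05, adjusted p = 0.614 with an estimated correlation). Of 18, 4 were higher, Dnah11 (1.15-fold), Ccdc153 (1.18-fold), Spag6l (1.11-fold) and Tmem212 (1.20-fold), 14 did not pass, and 12 were higher adjusted over the list alone. Alveolar type 2 markers stood higher (median 0.06, adjusted p = 0.016, adjusted p = 0.614 with an estimated correlation): 7 of 20 were higher, among them Cxcl15 (1.25-fold), Abca3 (1.28-fold) and S100g (1.23-fold), 2 were lower, among them the lung transcription factor gene Nkx2-1 (1.25-fold), 11 did not pass, and 8 and 2 passed adjusted over the list alone. That call ended without CD9KO number 1 (adjusted p = 0.060), and the median was 0.095 with the mean of all probe sets of a gene. Epithelial junction genes stood higher (median 0.06, adjusted p = 0.016, adjusted p = 0.614 with an estimated correlation), with 6 of 23 higher, among them Tjp3 (1.26-fold), Epcam (1.15-fold), Cldn8 (1.19-fold) and Pkp2 (1.13-fold), 17 not passing and 7 higher adjusted over the list alone. Epcam lost its call in 1 of 28 alternative fits and Pkp2 in 3, with lowest log2 differences of 0.11 and 0.066. Interstitial and fibrillar matrix genes stood higher (median 0.12, adjusted p = 0.0031, adjusted p = 0.614 with an estimated correlation). Of 27, 7 were higher, among them Col3a1 (1.57-fold), Col5a2 (1.26-fold) and Loxl1 (1.45-fold), 2 were lower, among them Fn1 (1.21-fold), 18 did not pass, and 11 and 2 passed adjusted over the list alone. Col5a2 had another probe set of opposite sign (log2 -0.11) and did not pass with the mean of both (log2 0.11, adjusted p = 0.429). Lipid and cholesterol synthesis genes stood higher (median 0.23, adjusted p = 2.0e-04, adjusted p = 0.614 with an estimated correlation): 9 of 22 were higher, among them Fasn (1.23-fold), Acaca (1.30-fold), Sqle (1.33-fold) and Cyp51 (1.28-fold), 2 were lower, 11 did not pass, and 13 and 3 passed adjusted over the list alone.

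Immune, muscle and stress lists also differed between the knockouts. Neutrophil markers stood higher in CD151KO (median 0.35, adjusted p = 0.0038, adjusted p = 0.614 with an estimated correlation): 4 of 10 were higher, S100a8, S100a9, Cxcr2 (1.67-fold) and Csf3r (1.64-fold), 6 did not pass, and 6 were higher adjusted over the list alone. With no filter the median was 0.22. B and plasma cell markers stood higher (median 0.35, adjusted p = 0.023, adjusted p = 0.741 with an estimated correlation) with 0 of 17 passing by limma, 3 at an unadjusted p under 0.05 and 0 adjusted over the list alone. On this list both number 1 arrays lay above the other 12, and its call ended without CD151KO number 1 (0.333) or 3 (0.061), CD9KO number 2 (0.069) or 3 (0.053), or both number 1 arrays (0.276). Without CD151KO number 1, or without both number 1 arrays, the median fell to 0.16. Mesothelial markers stood higher (median 0.21, adjusted p = 0.0045, adjusted p = 0.614 with an estimated correlation) with 0 of 10 passing by limma, 4 at an unadjusted p under 0.05 and 0 adjusted over the list alone, and the median was 0.14 without CD9KO number 2. Cardiac muscle genes stood lower in CD151KO (median -0.25, adjusted p = 0.0038, adjusted p = 0.667 with an estimated correlation), with 3 of 18 lower in either adjustment, all genes or the list alone, namely Hspb7 (1.40-fold), Myh6 (1.47-fold) and Myl3 (1.20-fold). The median was -0.16 with the mean of all probe sets of a gene. The glucocorticoid response stood lower (median -0.29, adjusted p = 0.0025, adjusted p = 0.614 with an estimated correlation), with 3 of 14 lower, Nfkbia (1.13-fold), Per1 (1.24-fold) and Mt2 (1.61-fold), and 8 lower adjusted over the list alone. Oxidative stress genes stood lower (median -0.09, adjusted p = 0.016, adjusted p = 0.667 with an estimated correlation), with 2 of 19 lower, Ephx1 (1.12-fold) and Gsta3 (1.26-fold), and 2 adjusted over the list alone. This call ended without CD9KO number 4 (adjusted p = 0.253, median -0.054). The median was -0.19 without CD151KO number 3 and -0.14 without CD9KO number 1, 2 or 5. The unfolded protein response stood lower (median -0.11, adjusted p = 0.0052, adjusted p = 0.667 with an estimated correlation) with 0 of 20 passing by limma, 7 at an unadjusted p under 0.05 and 0 adjusted over the list alone, and ended with the mean of all probe sets of a gene (0.087, median -0.061). Both number 1 arrays lay below the other 12 on this list. Oxidative phosphorylation genes stood higher (median 0.07, adjusted p = 0.0057, adjusted p = 0.638 with an estimated correlation), with 1 of 24 higher, Cox6c (1.07-fold, with another probe set of opposite sign), in either adjustment. The list median was 0.041 with the mean of all probe sets. Cytosolic ribosomal proteins stood higher (median 0.06, adjusted p = 0.0015, adjusted p = 0.614 with an estimated correlation), with 2 of 13 higher in either adjustment, Rpl11 (1.09-fold) and Rps14 (1.08-fold), and both number 1 arrays lay above the other 12 on it.

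Leaving out CD151KO number 1 or 2 or CD9KO number 5 brought the 1313 genes to 694, 856 or 682. Of the 71 passing genes named for this comparison, leaving out CD151KO 1 to 5 ended 20, 14, 8, 6 and 6 calls. Leaving out CD9KO 1 to 5 ended 8, 4, 16, 16 and 16, and wild type 3, 4 and 5 ended 8, 4 and 4, at adjusted p from 0.050 to 0.121.

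Against wild type, 15 genes passed in the same direction in both knockouts. Actg2 rose 1.31-fold in CD151KO and 1.42-fold in CD9KO, and Eln rose in both (log2 0.56, SE 0.11, and 0.66, SE 0.11). Fndc4 (log2 0.28 and 0.25), the epithelial splicing regulator gene Esrp2 (0.23 and 0.30), and Lipe, which codes for hormone-sensitive lipase (0.45 and 0.54), were the others among the 5 risen genes with the smallest adjusted p, of 8 in all. The first 5 of the 7 that fell were Sbds (log2 -0.20 and -0.19), Coq10b (-0.34 and -0.23), the replication gene Mcm5 (-0.21 and -0.19), Crim1 (-0.32 and -0.39) and the histone gene H3f3a (-0.30 and -0.31). Mfap5 (log2 0.61 and -0.33) and Gstt3 (0.27 and -0.25) rose in CD151KO and fell in CD9KO. Independent lists of these sizes would share 1.70 risen and 1.10 fallen genes, and shuffled deviations from the group means, which keep the shared wild type arrays and hold no effect, shared 0 in each of 100 shuffles (limma). In the shuffles only 0.02 and 7.22 genes passed per comparison on average, so this 0 does not measure what the shared arrays add. At an unadjusted p under 0.05 in both, 452 genes had the same direction, against a mean of 171 and a highest of 1013 in the shuffles. With the wild type arrays split so that each knockout had 2 of its own, 0 to 1 genes passed in both over 6 splits. Each comparison then had fewer arrays, and 4 to 62 genes passed in CD151KO and 1 to 1922 in CD9KO, so the splits do not separate shared controls from lower power. Across genes, which are not independent replicates, the log2 changes of the knockouts had a correlation of 0.307 (0.563 in the shuffles) and a covariance of 0.0047 (0.0041 in the shuffles). Leaving out wild type 1, 3 or 4 brought the 15 to 6, 5 or 1, leaving out CD151KO 3, 4 or 5 to 5, 3 or 3, leaving out CD9KO 3 or 5 to 6 or 8, and leaving out both number 1 arrays to 4. Gene lists share the wild type arrays too. The integrin and hemidesmosome, smooth muscle, adipose, cardiac muscle and unfolded protein response lists passed as higher in both knockouts, and immediate early genes as lower. Of these, only the cardiac muscle and unfolded protein response lists passed between the knockouts. What the shared arrays add to these list calls was not tested. Nor was what a technical difference, seen in the lower BioB control of the wild type arrays, adds to the genes and lists shared by both knockouts.

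The genes around each knocked-out gene were compared with all others. Within 20 Mb of Cd151 in the GRCm38.p6 gene table, 7 of 246 genes passed, against 92 of 12683 others (odds ratio 4.01, 95% interval 1.55 to 8.72, two-sided Fisher exact p = 0.0028, adjusted p = 0.045 over 16 such tests). The odds ratio was 4.61 within 10 Mb (adjusted p = 0.072) and 5.53 within 5 Mb (adjusted p = 0.060), with 4 genes that passed in each, and 2.50 for genes at an unadjusted p under 0.001 (adjusted p = 0.112), so none of these passed. Without both number 1 arrays, chosen after seeing the data, the odds ratio was 6.90 (adjusted p = 0.0051). The 7 genes were Cracr2b, the next protein-coding gene (log2 -0.25), Tspan4, 2 genes away (-0.78), Gm33248 (-0.67), Lrrc27 (0.50), Stk32c (0.64), Sec23ip (-0.21) and Scnn1b (0.25), the last a sodium channel subunit gene. Cracr2b, Lrrc27, Sec23ip and Scnn1b were chosen after their values were seen. Of the 7, Gm33248 also passed in CD9KO (log2 -0.32, adjusted p = 0.047). Around Cd9, 15 of 232 genes passed in CD9KO against 696 of 12697 others (odds ratio 1.19, 95% interval 0.652 to 2.02, Fisher exact p = 0.468, adjusted p = 0.808). Among these 15 were Cd163 (log2 0.73), Mfap5 (-0.33) and Kdm5a (-0.55), which are named above for CD9KO.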

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

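No test in this part was chosen after its result was seen. Each value here is the highest or lowest of its group, with a gap to the nearest other array that exceeded Dixon's 95% critical value for the group's size. Chance alone gives this in about 1 in 20 groups, and it was met by 32 of 678 groups of gene signals (226 genes in 3 groups), 3 of 69 groups of gene list means and 0 of 21 groups of array measures. The 32 signals were spread over 12 arrays, with the most on wild type number 1 (5) and on CD151KO numbers 1 and 5 (4 each).

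On wild type number 1 the B cell gene Bank1 measured 338, against 127 to 158 on the other wild type arrays, and on CD151KO number 1 it measured 385, against 116 to 182. The plasma cell gene Mzb1 measured 540 on CD151KO number 1 (others 349 to 369). Csf3r, the receptor gene for granulocyte colony-stimulating factor, measured 263 on wild type number 1 (others 162 to 169). That array was also apart for the ribosomal protein gene Rpl27 at 7096 (others 6349 to 6405), the ATP synthase gene Atp5c1 at 4437 (others 4001 to 4026) and the cytochrome c gene Cycs at 3307 (others 3569 to 3594). On CD151KO number 1 the clock gene Per2 measured 307 (others 624 to 737) and the lipid droplet gene Plin4 114 (others 151 to 166).

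Among the other wild type arrays, number 3 was apart for Cnn1 at 474.5 (others 405 to 417), Fasn at 1847 (others 1562 to 1600) and the B cell gene Vpreb3 at 307 (others 349 to 356). Number 4 was apart for the cardiac actin gene Actc1 at 2415 (others 1911 to 1968) and the fibronectin gene Fn1 at 2074 (others 1858 to 1884). Number 5 was apart for the endothelial cadherin gene Cdh5 at 2419 (others 2550 to 2574) and Lipe at 112 (others 125 to 127).

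In CD151KO, the knocked-out gene itself was lowest on number 3, with Cd151 at 1027 (others 1061 to 1072), and Fndc4 measured 57.4 there (others 61.3 to 62.9). Number 2 was apart for the ciliated cell gene Tmem212 at 1937 (others 2217 to 2331). Number 5 was apart for the haptoglobin gene Hp at 12423 (others 10652 to 10831), the laminin gene Lamb1 at 1603 (others 1315 to 1386), Pdia4 at 953 (others 834 to 866) and Mfsd2a at 214 (others 106 to 134). The mean log2 signal of interstitial and fibrillar matrix genes was 9.62 on number 5 (others 9.55 to 9.57), and that of basement membrane genes was 9.60 on number 3 (others 9.64 to 9.66).

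In CD9KO, number 4 was apart for Fkbp5 at 2107 (others 1294 to 1418), the glutathione synthesis gene Gclm at 1590 (others 1090 to 1232) and Myrip at 1672 (others 872 to 1097), and its mean log2 signal of oxidative stress genes was 10.69 (others 10.25 to 10.33). Number 1 was apart for Bdnf at 379 (others 278 to 305) and Hlf at 409 (others 324 to 332). Number 2 was apart for Cyp4b1 at 10770 (others 10064 to 10199), Fst at 97.1 (others 139 to 155) and Tef at 3104 (others 2957 to 2993), and number 3 for the small heat shock gene Cryab at 4680 (others 4149 to 4219).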

How the results depend on the processing

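Leaving out the 2 arrays that stand apart and adding the residual component were chosen after the results were seen. Cd151 and Cd9 kept direction and call in the 28 alternative fits run for single genes (with 1 array left out, Cd151 -2.34 to -2.27 and Cd9 -3.61 to -3.55 against wild type, and -2.23 to -2.20 and 3.57 to 3.64 between the knockouts). The change of Cd151 was -1.60 and -1.59 with the mean of its 6 probe sets, which takes in the pair with wild type signals of 55.5 and 136. Genes passing in CD151KO against wild type numbered 101, and 152 with every probe set tested, 39 with only the compared groups in the fit, 335 with array weights, 14 at 1.5-fold or more, 57 without moderation, 45 without the 2 arrays and 302 with the residual component. In CD9KO against wild type 715 became 1691 with every probe set (727 rose), 1090 with array weights, 26 at 1.5-fold or more, 313 without moderation, 405 without the 2 arrays and 2449 with the residual component. Between the knockouts 1313 became 64 at 1.5-fold or more and 2615 with the residual component. The 15 genes changed in both knockouts became 9 with no filter, 72 with array weights, 8 without moderation, 4 without the 2 arrays, 101 with the residual component, and 0 to 1 with wild type split. That component held 33.2% of the residual variance and comes from the residuals it then reduces, so its counts are too high. With every probe set tested, probe sets and not genes were counted, the fold limit keeps part of the calls, and the smaller fits and the split use fewer arrays. For no filter, array weights, the block and no moderation the cause was not tested. With 1 array left out, the counts ran from 24 (wild type 4) to 98 (CD9KO 4), 158 (wild type 3) to 865 (CD151KO 1), 682 (CD9KO 5) to 1939 (wild type 1), and for both knockouts 1 (wild type 4) to 14 (CD9KO 1). Gene lists passing ran from 11 (CD151KO 5) to 18 (wild type 4), 7 (wild type 1) to 12 (wild type 3) and 14 (CD151KO 1) to 16 (CD9KO 5), and numbered 0, 0 and 0 with an estimated correlation (camera, 8, 1 and 3 at an unadjusted p under 0.05). At the preset correlation 8 of 16, 6 of 11 and 11 of 15 passed in each alternative run for lists. Lists were not run with a pseudocount of 64, median centring, the filter at the 60th percentile, only the compared groups, no trend, array weights or no moderation.

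Replicate numbers were not taken to pair the samples in the main fit. Same-numbered deviations correlated above 0.1 in 3 of 4 pairs of wild type and CD151KO, 1 of 4 of wild type and CD9KO, and 2 of 5 of the knockouts. Their mean correlations of 0.294, 0.085 and 0.035 lay above those of other numbers (-0.063, -0.022 and -0.0096), and 2, 2 and 1 arrays correlated best with their own number. An effect shared by samples of the same number is therefore not excluded, above all between wild type and CD151KO. With the replicate block 109, 1591 and 1821 genes passed, 29 in both knockouts, and 18, 10 and 15 lists, with B and plasma cell markers in CD9KO not passing (adjusted p = 0.0780). Over named genes and alternatives, 7210 results kept their side of the threshold, 204 came to pass and 838 no longer passed. Of passing genes named as list members or as changed in both knockouts, few kept their call in each alternative fit that tested them. They were 2 of 20 in CD151KO against wild type, 11 of 45 in CD9KO against wild type and 29 of 53 between the knockouts. Of results that had passed, 1 reversed, Lamc1 in CD9KO against wild type with the mean of all its probe sets (log2 -0.029, adjusted p = 0.783, the highest over its alternatives), and the cause was not tested. Of those that had not passed, 4 of 3408 changed sign, and all 4 stayed short of the threshold. For gene lists 2690 kept their side, 47 came to pass and 98 no longer passed. Medians of lists that had passed changed sign in 0 of 924 cases (camera) and those of the others in 133 of 1911. Of these 133, 3 then passed with a median below 0 in CD151KO against wild type: heat shock and chaperone genes without wild type 1 (median 0.08 to -0.14, adjusted p = 0.017), B and plasma cell markers without CD151KO 1 (0.02 to -0.12, 0.031) and the oxidative stress response without CD151KO 3 (0.00010 to -0.04, 0.029). The odds ratio near Cd151 was 4.61 at 10 Mb, 5.53 at 5 Mb and 2.50 at an unadjusted p under 0.001, none of which passed (adjusted p = 0.072, 0.060 and 0.112). The smaller windows hold fewer genes, and for the unadjusted p the cause was not tested. It was 6.90 without the 2 arrays (adjusted p = 0.0051), and near Cd9 it was 1.41, 0.913, 1.19 and 1.57. The median of all genes stayed within 0.014 of 0 under each scaling. Signal over background limits the folds of weakly expressed genes.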

Other observations

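The clock phase test, the test of clock genes without the number 1 arrays, and the values of Ccnd1 were chosen only after the results were seen. A few other members of the tetraspanin family passed in CD9KO lungs, though their list did not. Tspan1 fell 1.21-fold against wild type, from 1207 ± 26.2 (SD, n = 4) to 999 ± 64.7 (n = 5) (log2 -0.27, SE 0.06, limma adjusted p = 0.018), and Cd82 fell 1.18-fold, from 1998 ± 146 to 1687 ± 50.3 (adjusted p = 0.019). They were among 3 that fell of 24 tetraspanins and partners, 21 did not pass, and adjusted over the list alone 0 rose and 4 fell (median -0.03, camera adjusted p = 0.375, adjusted p = 0.837 with an estimated correlation). In CD151KO, Tspan4 was the only 1 of the 24 to pass against wild type, and adjusted over the list alone 1 rose and 1 fell (camera adjusted p = 0.898, and 0.968 with an estimated correlation). Tspan4 lies 2 genes from Cd151, so its fall may belong to the position of the gene and not to the family. Between the knockouts Tspan1 was 1.30-fold higher in CD151KO (1301 ± 93.7, adjusted p = 0.0014). It was among 3 higher, with Tspan4 the only 1 lower, and 8 were higher and 1 lower adjusted over the list alone (camera adjusted p = 0.311). The call of Tspan1 against wild type ended without wild type number 3 (adjusted p = 0.051), and that of Cd82 without wild type number 3 (0.060) or CD9KO number 5 (0.054) and with the mean of its probe sets (0.070).

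A few single genes of TGF-beta signalling, endothelium, airway secretory cells and basement membrane passed in comparisons in which their lists did not. For scale, 715 of all 12986 genes passed in CD9KO against wild type, and 1313 between the knockouts. Tgfb2 fell 1.44-fold in CD9KO, from 538 ± 85.4 (n = 4) to 367 ± 37.7 (n = 5) (log2 -0.52, SE 0.10, limma adjusted p = 0.014), and passed in the 28 alternative fits run for single genes. Of 23 genes on its list 2 rose, 2 fell and 19 did not pass, with 4 risen and 2 fallen adjusted over the list alone (camera adjusted p = 0.456). Flt1, a receptor gene for vascular endothelial growth factor, rose 1.37-fold in CD9KO, from 1359 ± 170 to 1856 ± 55.6 (adjusted p = 0.011), though not with the mean of its probe sets (log2 0.23, adjusted p = 0.076). Of 22 endothelial markers 2 rose, 1 fell and 19 did not pass, with 3 and 1 adjusted over the list alone (camera adjusted p = 0.375). Between the knockouts, Flt1 (1.30-fold) and Ramp2 (1.24-fold) were lower in CD151KO, and the basement membrane genes Col4a4 (1.26-fold, adjusted p = 0.0049) and Lamb3 (1.27-fold, adjusted p = 0.0058) higher, and these 4 passed in the same 28 fits. Of 21 basement membrane genes 4 were higher and 17 did not pass, with 4 higher adjusted over the list alone (camera adjusted p = 0.221). Of the endothelial markers 1 was higher and 4 lower, with 3 and 4 adjusted over the list alone (camera adjusted p = 0.167). Bpifa1, a secreted protein gene of the upper airways, measured 10967 ± 1783 in CD151KO and 5777 ± 3210 in CD9KO (2.08-fold, log2 1.06, SE 0.25, adjusted p = 0.018), and did not pass without moderation (adjusted p = 0.054). Of 17 club and secretory cell markers 3 were higher and 1 lower in CD151KO, with 5 and 2 adjusted over the list alone (camera adjusted p = 0.266, and 0.688 with an estimated correlation).

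The clock genes that differed between CD151KO and wild type went in opposite directions by arm of the clock. Genes peaking with Arntl had positive log2 changes in 3 of 3 (mean 0.65) and genes of the opposite arm negative ones in 9 of 9 (mean -0.50), and the difference of the arm means per array was -1.87 ± 0.305 in CD151KO (n = 5) and -3.02 ± 0.306 in wild type (n = 4; two-sided exact permutation p = 0.0079, adjusted p = 0.012 over 3 comparisons). Without the number 1 arrays the median absolute change of the 9 clock genes that passed was 0.47, 77.9% of 0.60. These genes were chosen for passing with all arrays, so this value decides little. The difference of the arm means lay from -2.18 to -1.58 on the other CD151KO arrays. On the other wild type arrays it lay from -2.92 to -2.81, which argues against the number 1 arrays as the whole source. A shift of clock phase is a candidate explanation, found and tested on the same data. Whether it would come from the hour at which lungs were taken, which is not given in the sources used here, or from the loss of CD151 stays open, and CD9KO lay at -2.86 ± 0.115 (exact permutation p = 0.373 against wild type, n = 5 and 4).

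Genes that passed in CD151KO lay within 20 Mb of Cd151 with an odds ratio of 4.01, 2.85% of 246 genes against 0.725% of 12683 (two-sided Fisher exact p = 0.0028, adjusted p = 0.045 over 16 tests). The ratio was 4.61 within 10 Mb and 5.53 within 5 Mb, on 4 genes each (adjusted p = 0.072 and 0.060), and 2.50 for genes at an unadjusted p under 0.001 (0.112). Without the number 1 arrays the median absolute change of the 7 genes was 98.9% of that with all arrays. These genes were chosen for passing with all arrays, so this value decides little. With genes called anew without these arrays, chosen after seeing the data, the odds ratio was higher, as given above. That argues against the number 1 arrays as the source of the ratio. DNA of another strain kept around the knocked-out gene may account for some of the calls near Cd151. So may an effect of the knockout on its neighbours, which was not tested. The cells in which the knockouts were made and the backcrosses are not given in the sources used here. Near Cd9 the odds ratio of 1.19 had an interval of 0.652 to 2.02, which leaves the same explanation undecided there.

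Cardiac muscle genes, 18 of them above the signal filter in these lungs and 1 shared with another list, stood higher in CD9KO than in wild type (median log2 0.38, camera adjusted p = 1.4e-05, adjusted p = 0.771 with an estimated correlation). A single array is argued against as the source, since the lowest median on leaving out any array was 0.31, without CD9KO number 3, or 82.1% of that with all. The groups overlapped in the mean log2 signal of the list. CD9KO number 5 (8.64) lay below wild type number 4 (8.68), and the other CD9KO arrays (8.82 to 9.12) lay above every wild type array. CD151KO numbers 3 and 5 (8.91 and 8.998) lay within the CD9KO range, and numbers 1, 2 and 4 (8.59, 8.47 and 8.52) below every CD9KO array. The level therefore also varied between samples of a group. More cardiac muscle in the CD9KO samples is a candidate explanation that stays open. The 5 most abundant members, Actc1, Myl7, Myh6, Myl4 and Tnnt2, with mean signals of 2434, 1883, 1430, 1309 and 922, all had positive changes (5 of 5), but so had 17 of the 18, all except Myh7 (log2 -0.23, limma adjusted p = 0.310), so any 5 members would have given at least 4 and the test decides nothing. Whether such muscle came with the dissection or belongs to the lung veins of these mice, and so to the genotype, was not tested.

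Other splits of the same arrays into groups of the same sizes seldom gave as many genes, with 100 of 126 possible splits drawn per comparison. For CD151KO against wild type 3 of 100 splits gave 101 genes or more, the real one included, a share under 0.05 of those drawn. The splits not drawn could move this share, so chance is not excluded. The highest other split gave 400. It set wild type number 1 and CD151KO numbers 1, 2 and 3 against the rest, which points to a structure of the samples apart from their groups. For CD9KO against wild type 1 of 100 splits, the real one, gave 715, and the highest other gave 106. For CD151KO against CD9KO 1 of 100, the real one, gave 1313, and the highest other gave 2.

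The probe sets of the cyclin gene Ccnd1, chosen after their values were seen, differed in direction. The probe set with the lowest signal rose in CD151KO, from 324 ± 30.5 (n = 4) to 537 ± 57.8 (n = 5) (log2 0.70, SE 0.08, limma adjusted p = 5.1e-04 over all probe sets), and measured 292 ± 20.4 in CD9KO. The others, with wild type signals of 2574 ± 135 and 2338 ± 286, had log2 differences of -0.13 and -0.28 (adjusted p = 0.586 and 0.209). Between the knockouts all 3 passed, the first higher in CD151KO (log2 0.84, adjusted p = 1.9e-05) and the others lower (-0.29 and -0.40, adjusted p = 0.0094 and 0.0079).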
